A study of Citrullus lanatus with 18 samples.

How the data were processed

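RNA from watermelon flesh of 3 genotypes at 2 ages was sequenced on an Illumina NovaSeq instrument, per the series' design text, with 3 libraries in each of 6 groups. Groups and replicate numbers were taken from the sample titles. The authors deposited a table of TPM per gene: the unit was inferred from the deposited values, which sum to between 970421 and 986784 in each library and carry 2 decimals. The submitters' processing notes name Cufflinks, HISAT2, StringTie and TopHat2 with no version or role, and the genome build and annotation are not given in the sources used here. TPM divides each gene's reads by transcript length and scales each library to a fixed sum, so a few abundant genes lower the values of all others. Such values hold no counts, so no depth and no counting interval can be given. The columns of the later age are written 20 in the table and 18 DAP in the sample labels. They were assigned to 18 DAP because the labels give no other age, and which number is right is not settled here. Gene descriptions come from the table, where 2976 genes are unknown proteins. No genome was used here, so no coordinates are given. Close copies within gene families can share reads, and how the authors split these is not stated.

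Values were used as deposited and transformed to log2(TPM + 1). Genes with a mean of at least 1 TPM in at least 1 group were tested (17150 genes). One limma fit (limma 3.58.1, R 4.3.3, statmod 1.5.0) of 6 group means to all 18 libraries, with a trended, robust prior on the variance, gave every comparison, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A design for counts had been written as well and was not used, since the table holds TPM. Nothing in the labels says that the libraries of a group came from separate plants or fruit, so p-values measure only the spread between these libraries, which can be technical. A change in both OE lines needed a call with one sign in each. The lists of genes (34 written, 32 with at least 5 tested members) were fixed as search patterns on the descriptions and tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. The lists of SnRK2 kinases and of organelle-encoded genes matched no description.

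The design, the lists, the alternatives and the rule for named genes were written before the data were examined. Genes could be named with an informative description and a mean of at least 5 TPM over all libraries. For the changes at 10 DAP and at 18 DAP in both lines, for 18 against 10 DAP in WT and for the difference in change, the rule took the 6 called genes with the largest fold change in each direction, up to 4 called members of each list whose test passed and up to 2 of each other list. It also took the most abundant member of the ABA perception, ABA synthesis, sucrose and galactose, sugar transporter and carotenoid lists. Genes named outside it are said to be so.

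The code was tested on simulated data. For OE1 against WT at 18 DAP with 17150 genes, 45.0% of genes changed by 1 on the log2 scale and 86.6% of those changed by 2 were recovered, with 4.56% false calls. The simulated noise was normal and independent between genes, with no library standing apart. These shares test the code and may not hold for the deposited data. Comparisons that share WT libraries were set beside 100 simulations of unchanged groups, made by reassigning residuals. With 3 WT libraries at each age, the controls were too few to be split. Alternatives were quantile normalization, median centring, no filter on low values, a filter at a mean of 5 TPM, pseudocounts of 0.1 and 5, no variance trend, the compared libraries alone, the replicate number as a block, an added minimum log2 fold of 1 and each library left out in turn. Leaving out both libraries that stood apart was added after the data were seen.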

Results

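Gene expression was measured by RNA sequencing in the flesh of watermelon (Citrullus lanatus) fruit from wild-type plants (WT) and from plants of the transgenic lines OE1 and OE2, which overexpress the protein kinase gene ClSnRK2.3. Kinases of the SnRK2 family act in signalling by the hormone abscisic acid (ABA). Fruit was sampled at 10 and 18 days after pollination (DAP), with 3 libraries per genotype and age and 18 libraries in all. The deposited table holds 22596 genes as TPM, transcript abundance scaled to a fixed sum per library, which keeps no sequencing depth, so the depth behind each value is unknown. The values summed to between 970421 and 986784 per library, and no library repeated another. Levels below are mean TPM ± SD over n = 3 libraries unless each library is given, and fold changes are differences of mean log2(TPM + 1), which understate the change of low genes. No gene description in the table names an SnRK2 kinase, so the level of the overexpressed gene was not checked here.

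The first principal component held 58.7% of the variance and separated the ages. Its mean was 101 ± 4.19 in WT at 18 DAP, 73.7 ± 4.43 in OE1 and 47.5 ± 16.4 in OE2 (SD, n = 3). A pair of libraries stood apart. WT library 1 at 10 DAP correlated at a mean r of 0.932 across genes with the other WT libraries of its age and of 0.971 with those of OE2. OE2 library 1 at 18 DAP correlated at 0.898 with its siblings, and 33 genes were listed at 0 there that reached at least 20 TPM in both siblings, against 4 or fewer in any other library. The composition also differed between groups: the 10 most abundant genes of a library took 14.8% ± 0.677 of the TPM in WT at 18 DAP and 10.2% ± 0.611 in OE1 at 18 DAP (SD, n = 3).

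**Figure D1:**
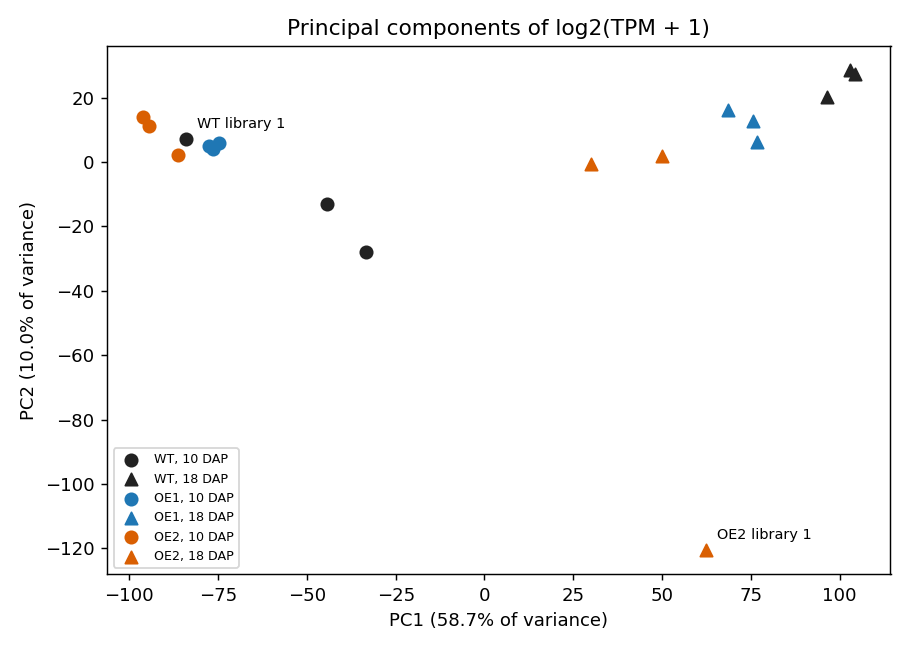
Each point is a library placed by its first (x axis) and second (y axis) principal component of log2(TPM + 1), in component units, coloured by genotype and shaped by age. WT library 1 at 10 DAP lies at -83.9 on the x axis among the OE libraries, and OE2 library 1 at 18 DAP lies at -121 on the y axis.

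The development of WT flesh was examined by comparing 18 with 10 DAP. The desiccation-related protein PCC13-62-like (Cla97C06G113860) rose from 6.403 ± 1.27 TPM to 3657 ± 721 TPM, a log2 fold change of 8.95 (SE 0.38, adjusted p = 5.98e-10). A pathogenesis-related protein 1-like gene (Cla97C02G034010) rose from 56.6 ± 48.8 TPM to 2868 ± 427 TPM, and a nodulin-like transporter gene (Cla97C02G031010) from 16.8 ± 13.7 TPM to 3306 ± 475 TPM. In the opposite direction, the proline-rich protein DC2.15 (Cla97C10G187390) fell from 1798 ± 824 TPM to 0.987 ± 0.2899 TPM, a change of -9.74 (SE 0.30, adjusted p = 2.60e-11). The gibberellin-regulated protein 4-like gene (Cla97C10G197900) fell from 574 ± 192 TPM to 1.17 ± 0.687 TPM, and the MLP-like protein 423 gene (Cla97C05G107250) changed by -8.50.

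Of the lists of genes fixed before the data were examined, carotenoid metabolism, which makes the flesh pigments, was placed higher at 18 DAP in WT: 19 of 40 were higher and 8 lower (20 and 8 adjusted over the list alone; 24 and 5 after median centring). Its list test gave adjusted p = 0.000111, and adjusted p = 0.262 with an estimated correlation. Beta-carotene hydroxylase, which forms xanthophylls, rose from 167 ± 55.2 TPM to 971 ± 119.5 TPM (Cla97C05G090480), and a second copy (Cla97C01G002480) changed by 5.48. Of 9-cis-epoxycarotenoid dioxygenase genes, which encode the step that commits carotenoids to ABA, Cla97C07G137260 rose by 4.65 and Cla97C07G137780 fell from 29.8 ± 4.82 TPM to 3.04 ± 1.31 TPM. For chlorophyll and photosynthesis, 38 of 86 were higher and 3 lower (38 and 3 adjusted over the list alone). Camera gave this list adjusted p = 8.98e-09, and adjusted p = 0.486 with an estimated correlation. The small chain of ribulose bisphosphate carboxylase (Cla97C05G104530), the enzyme that fixes carbon dioxide, was at 35.2 ± 54.3 TPM and 312 ± 155 TPM. Among NAC transcription factors 19 of 56 were higher and 16 lower (20 and 16 adjusted over the list alone; 26 and 10 after median centring). For the list as a whole the test gave adjusted p = 0.00944, and adjusted p = 0.262 with an estimated correlation. The NAC domain-containing protein 55 (Cla97C10G190590) rose by 6.02. Among heat shock proteins 32 of 86 were higher and 15 lower (33 and 17 adjusted over the list alone; 41 and 10 after median centring). This list was placed with adjusted p = 3.59e-05, and adjusted p = 0.327 with an estimated correlation. A class I heat shock protein-like gene (Cla97C07G132190) rose by 4.85.

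Several lists were placed lower at 18 DAP in WT. Among cell wall loosening genes 10 of 142 were higher and 93 lower (10 and 95 adjusted over the list alone). In the list test it had adjusted p = 1.27e-07, and adjusted p = 0.262 with an estimated correlation. A pectate lyase gene (Cla97C03G054380), whose product cuts pectin, was 154 ± 51.03 TPM at 10 DAP and 0.0800 ± 0.0265 TPM at 18 DAP, and expansin-A8-like (Cla97C11G212620) changed by -6.90. Among cell division genes 5 of 113 were higher and 69 lower (5 and 71 adjusted over the list alone; 10 and 63 after median centring). The corresponding list test gave adjusted p = 3.59e-05, and adjusted p = 0.546 with an estimated correlation. A kinesin-like gene (Cla97C08G150480) fell from 32.9 ± 26.01 TPM to 0.707 ± 0.166 TPM. Among histones 1 of 35 was higher and 27 lower (1 and 27 adjusted over the list alone). Tested as a list, it gave adjusted p = 3.59e-05, and adjusted p = 0.546 with an estimated correlation. A histone H2B gene (Cla97C01G012830) changed by -3.13. Among cytosolic ribosomal proteins 2 of 154 were higher and 120 lower (2 and 122 adjusted over the list alone; 7 and 78 after median centring). As a list it passed with adjusted p = 7.66e-12, and adjusted p = 0.486 with an estimated correlation. Among pathogenesis-related proteins 6 of 88 were higher and 51 lower (6 and 51 adjusted over the list alone; 10 and 45 after median centring). Against all other genes the list had adjusted p = 0.000619, and adjusted p = 0.393 with an estimated correlation. Markers of cuticle and epidermis, a tissue the flesh sample could hold, also fell: 1 of 20 was higher and 15 lower (1 and 17 adjusted over the list alone). Its list test gave adjusted p = 0.00125, and adjusted p = 0.408 with an estimated correlation. The gene of protodermal factor 1-like (Cla97C09G183800) was 290.1 ± 200.1 TPM at 10 DAP and 8.74 ± 0.357 TPM at 18 DAP.

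Among sucrose and galactose genes in WT 10 of 61 were higher and 27 lower (10 and 29 adjusted over the list alone; 24 and 18 after median centring), among sugar transporters 5 of 59 were higher and 29 lower (5 and 29 adjusted over the list alone; 10 and 17 after median centring) and among ABA perception and signalling genes 5 of 20 were higher and 5 lower (5 and 5 adjusted over the list alone; 10 and 3 after median centring). The list tests did not pass (adjusted p = 0.915, 0.206 and 0.104). The most abundant member of the sucrose and galactose list, an alkaline alpha-galactosidase that releases galactose from raffinose sugars (Cla97C04G070460), rose from 994 ± 53.8 TPM to 1709 ± 230.4 TPM. The most abundant sugar transporter gene, a SWEET exporter (Cla97C01G000640), fell from 523 ± 234 TPM to 139 ± 38.4 TPM, a call lost with median centring (adjusted p = 0.0539) and without WT library 3 of 10 DAP or WT library 3 of 18 DAP (adjusted p up to 0.0657). The most abundant ABA receptor gene (Cla97C09G172410) rose from 95.5 ± 38.1 TPM to 418 ± 76.4 TPM, and a protein phosphatase 2C 56-like gene (Cla97C03G066470), of a family that holds ABA signalling back, rose by 2.75. In all, limma called 7917 of 17150 genes, 2249 higher and 5668 lower at 18 DAP. Quantile normalization gave 4158 higher and 3822 lower, and median centring 4192 and 4086, against a median change of all genes of -0.28. The same comparison called 7756 genes in OE1 (3159 higher) and 8012 in OE2 (2418 higher), with 4109 and 4154 higher after median centring.

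The effect of overexpression at 18 DAP was taken as the genes that differed from WT in each line with one sign. Among the largest falls were those of gibberellin 20-oxidase (Cla97C05G089570), an enzyme of gibberellin synthesis, with 3091 ± 1091 TPM in WT, 62.98 ± 82.7 TPM in OE1 and 48.4 ± 34.9 TPM in OE2, and of desiccation-related protein PCC13-62-like (Cla97C06G113860), with 3657 ± 721 TPM, 143 ± 75.2 TPM and 16.9 ± 6.46 TPM. Their log2 fold changes were -6.42 in OE1 and -6.35 in OE2 (adjusted p = 0.000429 and 0.000143) and -4.77 in OE1 and -7.73 in OE2 (adjusted p = 5.63e-06 and 1.63e-08). Organ-specific protein P4-like (Cla97C11G211230) fell from 121 ± 53.5 TPM to 9.48 ± 13.3 TPM and 2.58 ± 2.17 TPM, and subtilisin-like protease C1 (Cla97C07G132000) from 133 ± 31.4 TPM to 5.88 ± 6.94 TPM and 8.34 ± 7.31 TPM. A putative transcription factor (Cla97C10G194380) was listed at 0 TPM in each library of WT and 30.8 ± 19.7 TPM in OE1 and 115 ± 31.1 TPM in OE2. An expansin gene (Cla97C06G125700), whose product loosens cell walls, was 1.27 ± 0.531 TPM in WT, 41.3 ± 26.5 TPM in OE1 and 119 ± 72.4 TPM in OE2, a change of 4.08 in OE1 and 5.51 in OE2. A glycosyltransferase gene (Cla97C09G177180) changed by 4.84 in OE1 and 3.99 in OE2, from 3.14 ± 2.18 TPM in WT.

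**Figure D2:**
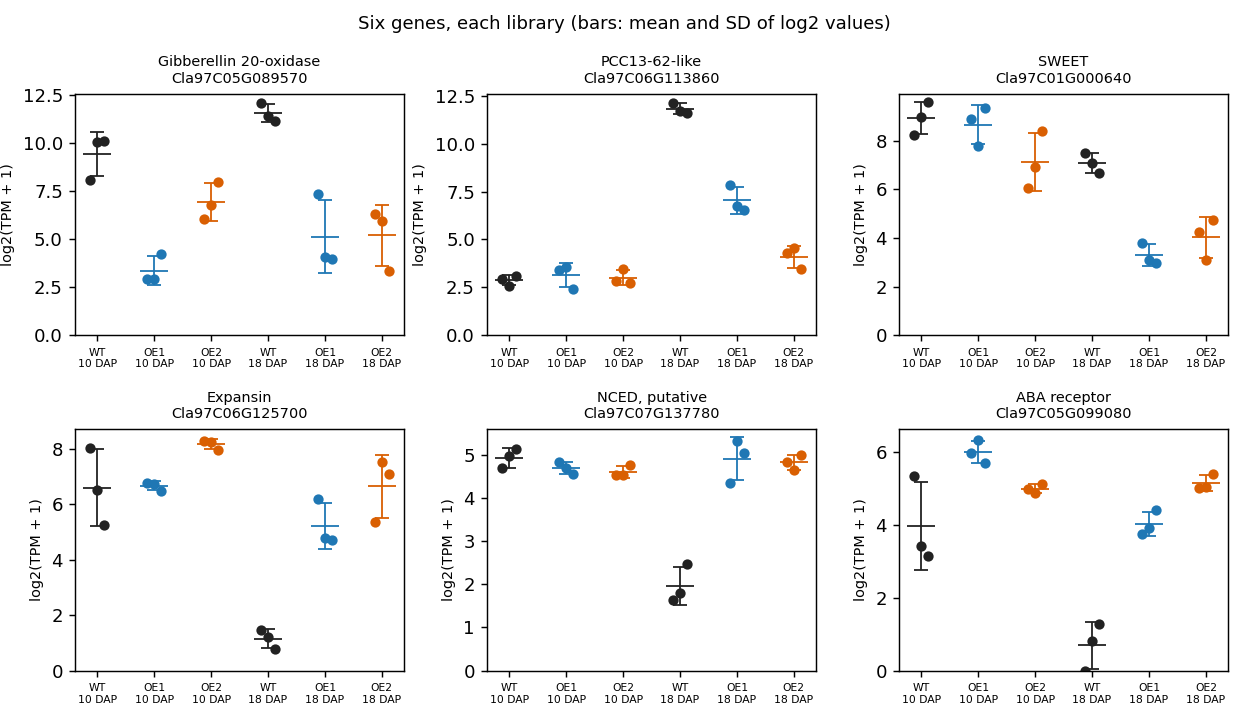
Each panel plots log2(TPM + 1) of a gene (y axis) in each library (points) by group (x axis), with bars at the mean and the SD of the log2 values. At 18 DAP every OE library lies below the WT libraries for gibberellin 20-oxidase, PCC13-62-like and the SWEET gene Cla97C01G000640, and above them for expansin, the 9-cis-epoxycarotenoid dioxygenase (NCED) and the ABA receptor Cla97C05G099080.

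Among ABA perception and signalling genes at 18 DAP, 2 were higher and 1 lower in both lines among 20 tested (2 and 1 adjusted over the list alone). An ABA receptor gene (Cla97C05G099080) was 0, 0.75 and 1.42 TPM in the WT libraries, 15.5 ± 3.98 TPM in OE1 and 34.4 ± 5.43 TPM in OE2. The PYL8-like ABA receptor (Cla97C01G000570) was higher by 1.44 in OE1 and 1.87 in OE2. The most abundant receptor gene (Cla97C09G172410) was lower, at 211 ± 25.5 TPM in OE1 and 137 ± 40.9 TPM in OE2 against 418 ± 76.4 TPM in WT, a call lost in a fit to the compared libraries alone (adjusted p = 0.0501) and without WT libraries 1 or 2 of 18 DAP or OE1 libraries 1, 2 or 3 of 18 DAP (adjusted p up to 0.116). Of the ABA synthesis genes, 1 was higher and 1 lower in both lines among 11 tested (2 and 1 adjusted over the list alone). The 9-cis-epoxycarotenoid dioxygenase gene Cla97C07G137780 was 3.04 ± 1.31 TPM in WT, 30.1 ± 9.88 TPM in OE1 and 27.5 ± 3.37 TPM in OE2, and another (Cla97C01G024630) changed by -1.63 in OE1 and -2.37 in OE2. Zeaxanthin epoxidase (Cla97C02G038200), the most abundant of that list, was 71.9 ± 8.36 TPM, 88.9 ± 1.62 TPM and 56.4 ± 22.9 TPM and passed in neither line. No list test passed for either group in either line.

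Among sucrose and galactose genes at 18 DAP, 6 were higher and 3 lower in both lines among 61 tested (6 and 3 adjusted over the list alone; 3 and 6 after median centring). An alkaline alpha-galactosidase gene (Cla97C11G223970) was lower, at 14.7 ± 2.91 TPM in OE1 and 14.6 ± 10.8 TPM in OE2 against 93.7 ± 5.64 TPM in WT, and an alpha-galactosidase gene (Cla97C11G218690) was higher by 1.53 in OE1 and 2.48 in OE2, a call lost with quantile normalization (adjusted p = 0.082) and with a pseudocount of 5 (adjusted p = 0.171). The most abundant alkaline alpha-galactosidase (Cla97C04G070460) changed by -0.60 in OE1 and -1.25 in OE2, past the threshold in OE2 (adjusted p = 0.000538) and not in OE1 (adjusted p = 0.0791). Both lines passed in limma under 3 of 20 alternatives. These were median centring (adjusted p = 0.0116), leaving out OE2 library 1 (adjusted p = 0.0219) and leaving out both libraries that stood apart (adjusted p = 0.0219). Quantile normalization gave adjusted p = 0.429 and a fit to the compared libraries alone 0.128. With a single library left out, adjusted p reached 0.236. Among sugar transporters 9 were higher and 6 lower in both lines among 59 tested (12 and 6 adjusted over the list alone; 5 and 8 after median centring). The SWEET gene Cla97C01G000640 was 9.13 ± 3.33 TPM in OE1 and 17.03 ± 9.16 TPM in OE2 against 139 ± 38.4 TPM in WT. A second SWEET gene (Cla97C01G001850) changed by -2.55 in OE1 and -2.35 in OE2, a call lost in a fit to the compared libraries alone (adjusted p = 0.0569) and without WT library 2 of 18 DAP or OE1 libraries 1 or 3 of 18 DAP (adjusted p up to 0.0704). An ethylene-forming 1-aminocyclopropane-1-carboxylate oxidase gene (Cla97C09G173910) was higher, at 1463 ± 115 TPM and 1439 ± 373 TPM against 409 ± 128 TPM.

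Among cytosolic ribosomal proteins at 18 DAP, 11 were higher and 0 lower in OE1, and 122 and 0 in OE2, among 154 tested (adjusted over the list alone, 9 and 0, and 125 and 0; after median centring, 1 and 3, and 74 and 0). The list test gave adjusted p = 0.34 in OE1 and 1.15e-23 in OE2, and adjusted p = 0.905 and 0.287 with an estimated correlation. Among histones 5 were higher and 0 lower in OE1, and 18 and 0 in OE2, among 35 tested (adjusted over the list alone, 9 and 0, and 26 and 0; after median centring, 1 and 0, and 13 and 0). Tested against other genes, the list had adjusted p = 0.0225 in OE1 and 1.61e-06 in OE2, and adjusted p = 0.905 and 0.648 with an estimated correlation. The histone call in OE1 ended with median centring (adjusted p = 0.0813), with the stricter filter (adjusted p = 0.0584) and without WT library 2 or OE1 library 1 (adjusted p = 0.127 and 0.115). A histone H1-like gene (Cla97C02G042560) was 146 ± 18.8 TPM in OE1 and 197 ± 69.9 TPM in OE2 against 38.02 ± 0.953 TPM in WT. Among cell wall loosening genes 29 were higher and 6 lower in OE1, and 53 and 10 in OE2, among 142 tested (adjusted over the list alone, 33 and 7, and 59 and 11; after median centring, 17 and 11, and 43 and 15). Camera returned adjusted p = 0.765 in OE1 and 0.000408 in OE2, and adjusted p = 0.905 and 0.336 with an estimated correlation. The pectate lyase gene Cla97C03G054380 was 13.2 ± 4.64 TPM in OE1, 32.1 ± 7.20 TPM in OE2 and 0.0800 ± 0.0265 TPM in WT. Among pathogenesis-related proteins 21 were higher and 1 lower in OE1, and 34 and 4 in OE2, among 88 tested (adjusted over the list alone, 29 and 5, and 43 and 7; after median centring, 11 and 3, and 27 and 5). As a list they had adjusted p = 0.2 in OE1 and 0.000233 in OE2, and adjusted p = 0.905 and 0.287 with an estimated correlation. In OE2 library 1, the median deviation from its siblings lay above that of all genes by 0.77 for ribosomal proteins, 1.09 for histones, 0.41 for wall loosening and 0.60 for pathogenesis-related proteins (log2). Without that library and WT library 1 of 10 DAP, left out after the data were seen, the OE2 list tests gave adjusted p = 4.81e-10, 0.0124, 0.343 and 0.229 in that order, which ended the latter pair of calls.

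Among carotenoid genes at 18 DAP, 2 were higher and 4 lower in OE1, and 2 and 12 in OE2, among 40 tested (adjusted over the list alone, 2 and 4, and 4 and 14; after median centring, 1 and 4, and 1 and 18). The list test gave adjusted p = 0.164 in OE1 and 0.000358 in OE2, and adjusted p = 0.905 and 0.287 with an estimated correlation. Beta-carotene hydroxylase (Cla97C05G090480) was 515 ± 27.4 TPM in OE1 and 467 ± 201 TPM in OE2 against 971 ± 119.5 TPM in WT, a call lost with quantile normalization (adjusted p = 0.0767), with median centring (adjusted p = 0.0586), in a fit to the compared libraries alone (adjusted p = 0.0883) and without WT libraries 1, 2 or 3 of 18 DAP or OE1 libraries 1, 2 or 3 of 18 DAP (adjusted p up to 0.121). Among chlorophyll and photosynthesis genes 3 were higher and 7 lower in OE1, and 4 and 16 in OE2, among 86 tested (adjusted over the list alone, 3 and 7, and 4 and 16; after median centring, 1 and 11, and 1 and 22). Tested against other genes, the list had adjusted p = 4.98e-08 in OE1 and 7.15e-06 in OE2, and adjusted p = 0.905 and 0.648 with an estimated correlation. Oxygen-evolving enhancer protein 2 (Cla97C07G137540) was 94.6 ± 45.9 TPM and 50.4 ± 12.1 TPM against 281 ± 88.3 TPM, a call lost without WT libraries 2 or 3 of 18 DAP or OE1 libraries 1 or 3 of 18 DAP (adjusted p up to 0.0638). Among heat shock proteins 9 were higher and 4 lower in OE1, and 12 and 25 in OE2, among 86 tested (adjusted over the list alone, 9 and 5, and 13 and 27; after median centring, 2 and 11, and 7 and 35). Camera returned adjusted p = 0.0225 in OE1 and 1.30e-05 in OE2, and adjusted p = 0.905 and 0.287 with an estimated correlation. The call in OE1 ended with quantile normalization (adjusted p = 0.11), with no filter (adjusted p = 0.059) and without WT library 2 or OE1 library 1 (adjusted p = 0.085 and 0.11). The median in OE1 was 0.05 although the test placed the list lower, while all genes had a median of 0.25. Among flavonoid genes 0 were higher and 2 lower in OE1, and 0 and 5 in OE2, among 13 tested (adjusted over the list alone, 0 and 2, and 1 and 5). As a list they had adjusted p = 0.00283 in OE1 and 0.00493 in OE2, and adjusted p = 0.0596 and 0.162 with an estimated correlation. In OE2 library 1 the median deviation from its siblings lay above that of all genes by 1.09 for chlorophyll and photosynthesis, 0.05 for carotenoid, 0.09 for heat shock and 0.36 for flavonoid genes (log2). A dihydroflavonol-4-reductase gene (Cla97C06G109680) changed by -1.87 in OE1 and -1.90 in OE2. A NAC domain-containing protein 78 gene (Cla97C03G067000) was higher by 2.04 in OE1 and 2.39 in OE2, and a SIEVE ELEMENT OCCLUSION B-like gene of the phloem list (Cla97C06G116220) was 0.243 ± 0.253 TPM in WT, 10.8 ± 7.24 TPM in OE1 and 20.9 ± 18.5 TPM in OE2.

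**Figure D3:**
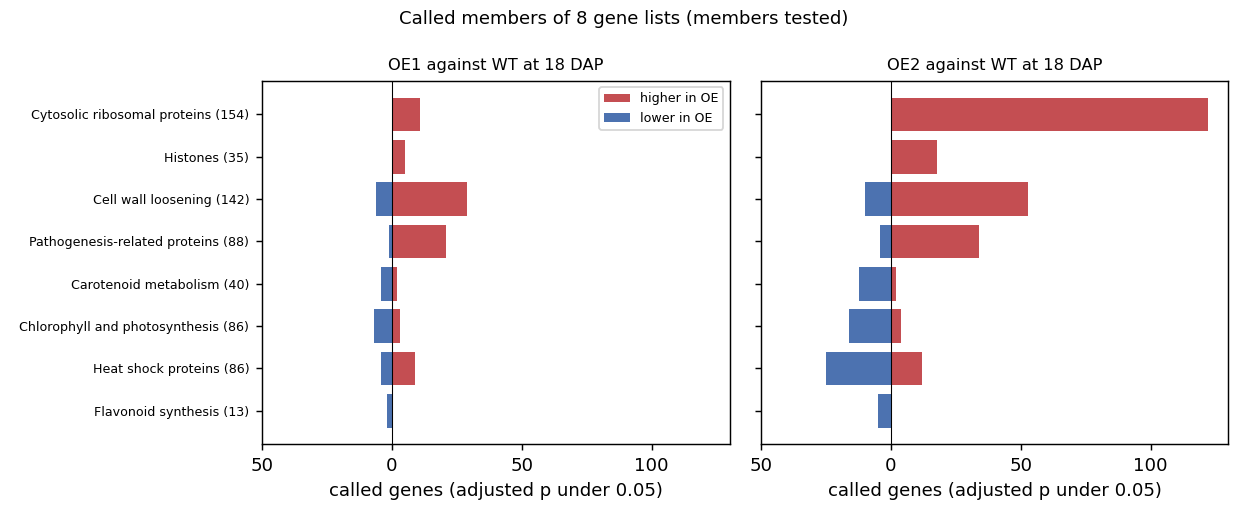
Bars count the members of each list (y axis, with the members tested) that limma called higher or lower (x axis, number of genes) in OE1 and in OE2 against WT at 18 DAP. Cytosolic ribosomal proteins had 11 higher members in OE1 and 122 in OE2, and 1 and 74 after median centring.

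At 18 DAP limma called 2254 genes in OE1 (1829 higher, 425 lower; 1246 to 1403 with each library of OE1 or WT left out in turn), 4350 in OE2 (3256 higher, 1094 lower) and 1827 in both lines with one sign (1467 higher, 360 lower). All genes had a median change of 0.25 in OE1 and 0.15 in OE2, and median centring, which evens the balance of higher and lower genes by construction, gave 578 higher and 795 lower in both lines (673 and 938 in OE1, 2067 and 2376 in OE2), and quantile normalization 564 and 547. Unchanged groups simulated against the shared WT libraries gave at most 0 common calls, and independent lists of these sizes would share 347 higher and 27.1 lower genes. A part of the excess may come from the shared controls. The fold changes of the lines correlated at r = 0.77 across genes against a mean of 0.44 and up to 0.80 in the simulations, which reached a higher r than the observed one. The covariance was 0.37 against a mean of 0.0590 and up to 0.173. Genes are not independent replicates. The common count was 4653 without OE2 library 1, with OE2 at 7500 genes, 1073, 1051 and 1196 without WT library 1, 2 and 3, and 1091 and 1161 without OE1 library 1 and 3. Without both libraries that stood apart it was 5651, and in a fit to the compared libraries alone 896, with 6291 genes called in OE1 and 1657 in OE2.

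At 10 DAP the lines were compared with WT in the same way. Gibberellin 20-oxidase (Cla97C05G089570) was lower in OE1, at 10.2 ± 6.297 TPM against 797 ± 457 TPM in WT, a change of -6.05 (SE 0.91, adjusted p = 0.00391). In OE2 it was 139.9 ± 97.5 TPM (adjusted p = 0.128). Subtilisin-like protease C1 (Cla97C07G132000) changed in OE1 by -4.26 (adjusted p = 0.0257), a call lost in a fit to the compared libraries alone (adjusted p = 0.128) and without WT libraries 2 or 3 of 10 DAP or OE1 libraries 1 or 2 of 10 DAP (adjusted p up to 0.158). Both genes were chosen for 10 DAP after their values were seen. The histone, cell division and chlorophyll lists were placed higher in each line, and limma called few of their genes singly with all libraries. Without both libraries that stood apart it called higher 28 histones in OE1 and 32 in OE2, 63 and 79 cell division genes, and 43 and 49 chlorophyll genes. WT library 1 was doubted because it lay near the OE libraries, so leaving it out tends to raise such calls. These counts are therefore no separate support for the list tests. Among histones 0 were higher and 0 lower in OE1 and 0 and 0 in OE2 among 35 tested (adjusted over the list alone, 0 and 0, and 27 and 0), with list test adjusted p = 1.04e-06 and 4.16e-10, and adjusted p = 0.659 and 0.608 with an estimated correlation. Among cell division genes 2 were higher and 1 lower in OE1 and 0 and 0 in OE2 among 113 tested (adjusted over the list alone, 0 and 0, and 47 and 3), with list test adjusted p = 0.000341 and 6.53e-07, and adjusted p = 0.887 and 0.948 with an estimated correlation. Among chlorophyll and photosynthesis genes 0 were higher and 0 lower in OE1 and 0 and 0 in OE2 among 86 tested (adjusted over the list alone, 0 and 0, and 24 and 0), with list test adjusted p = 0.00128 and 3.87e-05, and adjusted p = 0.887 and 0.948 with an estimated correlation. The cuticle and epidermis markers were placed lower in OE1, with 2 of 20 lower and 0 higher (adjusted p = 0.0003, and adjusted p = 0.38 with an estimated correlation). The phloem markers were placed higher, with 4 of 30 higher and 1 lower (adjusted p = 0.0351, and adjusted p = 0.887 with an estimated correlation). The phloem call ended without the pair of libraries that stood apart (adjusted p = 0.269), without WT library 1 or OE1 library 2 (adjusted p = 0.142 and 0.0828) and with a pseudocount of 0.1 (adjusted p = 0.0789). Carotenoid genes were placed lower in OE1 (adjusted p = 0.0049, and 0.075 without WT library 3) and in OE2 (adjusted p = 0.00101), with adjusted p = 0.406 and 0.513 with an estimated correlation. None of the most abundant genes of the ABA, sugar and carotenoid lists passed in both lines, except beta-carotene hydroxylase when WT library 1 was left out (adjusted p = 0.0148), and that gene and the most abundant ABA receptor gene without both libraries that stood apart (adjusted p = 0.000571 and 0.0169). The ABA receptor Cla97C09G172410 was 95.5 ± 38.1 TPM in WT, 79.1 ± 3.79 TPM in OE1 and 44.98 ± 3.76 TPM in OE2. The SWEET gene Cla97C01G000640 was 523 ± 234 TPM, 443 ± 214 TPM and 174 ± 143 TPM, and alkaline alpha-galactosidase Cla97C04G070460 994 ± 53.8 TPM, 972 ± 64.5 TPM and 775 ± 259 TPM. Zeaxanthin epoxidase Cla97C02G038200 was 30.8 ± 2.21 TPM, 21.8 ± 2.88 TPM and 28.5 ± 0.852 TPM, and beta-carotene hydroxylase Cla97C05G090480 167 ± 55.2 TPM, 96.9 ± 3.74 TPM and 94.1 ± 8.46 TPM.

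At 10 DAP limma called 645 genes in OE1 (306 higher, 339 lower) and 4 in OE2, of which 1 passed in both lines. The other genes called in OE2, all higher and named after their values were seen, were an amaranthin-like lectin gene (Cla97C03G055640, 1.71) and unknown proteins (Cla97C03G054360, 3.94, and Cla97C03G061370, 1.60). In a fit to the compared libraries alone each of these calls was lost (adjusted p = 0.254). The lectin gene also lost its call with quantile normalization (adjusted p = 0.066), with median centring (adjusted p = 0.0871) and without WT libraries 2 or 3 of 10 DAP (adjusted p up to 0.0713). The gene called in both lines, annotated as RNA polymerase II elongation factor ELL3 (Cla97C10G188990) and named after its values were seen, was 0.950 ± 0.303 TPM in WT, 2.09 ± 0.125 TPM in OE1 and 3.67 ± 0.683 TPM in OE2, and its call ended under 13 of 19 alternatives (adjusted p up to 0.235). At an unadjusted limma p under 0.05 there were 3268 genes in OE1 and 3776 in OE2. The adjusted counts of 645 and 4 thus do not show that OE2 differed less from WT. With other filters and pseudocounts the adjusted OE2 count ran from 1 (stricter filter) to 946 (pseudocount of 5). At the unadjusted threshold 1382 genes shared a sign in both lines. Unchanged groups simulated against the shared WT libraries gave a median of 87 and up to 2230 such genes. As many were reached in 1 of 100 simulations. The simulations drew residuals from all 18 libraries, while the shared WT libraries of 10 DAP varied more than the OE libraries of that age. The SD on the first principal component was 26.7 in WT, 1.45 in OE1 and 5.38 in OE2 (n = 3). All values from these simulations may thus understate the agreement that shared controls bring at 10 DAP. Without WT library 1 limma called 2651 genes in OE1, 3446 in OE2 and 1754 in both, a rise that leaving out the WT library nearest OE tends to bring. Without WT library 2 it called 72, 2 and 0. The OE1 count was 81 without WT library 3 and 100 and 78 without OE1 library 1 and 2. The OE2 count was 846 without OE2 library 3, with 74 in both lines. Without both libraries that stood apart the counts were 5886 in OE1, 7453 in OE2 and 4282 in both, and in a fit to the compared libraries alone 37, 1 and 0. The fold changes of the lines correlated at r = 0.56 across genes and at a mean of 0.54 and up to 0.90 in unchanged groups simulated against shared controls, with a covariance of 0.189 against a mean of 0.0735 and up to 0.183. Those simulations gave up to 1 common call, and independent lists would share 0.0714 higher genes.

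Whether the change from 10 to 18 DAP differed in the OE lines was tested as the mean change in OE1 and OE2 minus the change in WT. PCC13-62-like (Cla97C06G113860) rose from 6.403 ± 1.27 TPM to 3657 ± 721 TPM in WT, from 8.30 ± 3.45 TPM to 143 ± 75.2 TPM in OE1 and from 7.21 ± 2.26 TPM to 16.9 ± 6.46 TPM in OE2, a difference of -6.45 (SE 0.46, adjusted p = 2.47e-06). The alkaline alpha-galactosidase gene Cla97C11G223970 was 294 ± 122 TPM and 93.7 ± 5.64 TPM in WT and 814 ± 33.99 TPM and 14.7 ± 2.91 TPM in OE1, a difference of -3.68 (SE 0.49, adjusted p = 0.000466). A stem-specific protein TSJT1-like gene (Cla97C01G022730) differed by -4.57 and a SWEET gene (Cla97C06G127900) by -3.74. In the opposite direction, the 9-cis-epoxycarotenoid dioxygenase gene Cla97C07G137780 differed by 3.18 (SE 0.30, adjusted p = 3.01e-05), the pectate lyase gene Cla97C03G054380 by 4.50, the expansin gene Cla97C06G125700 by 3.98 and a lipid transfer protein gene (Cla97C07G143380) by 6.07.

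For the difference in change, 1 of 86 was higher and 18 lower (3 and 23 adjusted over the list alone; 0 and 17 after median centring) in the chlorophyll and photosynthesis list. Camera gave this list adjusted p = 2.06e-13, and adjusted p = 0.665 with an estimated correlation. The small chain of ribulose bisphosphate carboxylase (Cla97C05G104530) was 35.2 ± 54.3 TPM and 312 ± 155 TPM in WT and 172 ± 75.3 TPM and 72.1 ± 72.8 TPM in OE2. As the mean of both lines against WT it differed by -4.84, and oxygen-evolving enhancer protein 1 (Cla97C01G015370) by -3.24. Both calls ended without WT libraries 2 or 3 of 10 DAP or WT libraries 2 or 3 of 18 DAP (adjusted p up to 0.0846 and 0.0836). Among cytosolic ribosomal proteins 25 of 154 were higher and 0 lower (39 and 0 adjusted over the list alone; 2 and 0 after median centring). For the list as a whole the test gave adjusted p = 6.14e-10, and adjusted p = 0.685 with an estimated correlation. OE2 library 1 of 18 DAP, where this list lay 0.77 above all genes relative to its siblings (log2), enters this mean. Among cell wall loosening genes 26 of 142 were higher and 8 lower (42 and 10 adjusted over the list alone; 21 and 11 after median centring). This list was placed with adjusted p = 0.0112, and adjusted p = 0.677 with an estimated correlation. The wall loosening call ended without the pair of libraries that stood apart (adjusted p = 0.375), without OE2 library 1 of 18 DAP alone (adjusted p = 0.357), with no filter (adjusted p = 0.156) and with a pseudocount of 5 (adjusted p = 0.133). In all 1656 genes were called, 1184 higher and 472 lower, against 717 and 812 after median centring and 846 and 815 with quantile normalization. The count was 3809 without OE2 library 1 of 18 DAP, 2552 and 982 without WT library 1 and 2 of 10 DAP and 935 without WT library 2 of 18 DAP.

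The lines also differed from each other. At 18 DAP cytosolic ribosomal proteins were higher in OE2 than in OE1: 65 of 154 were higher and 0 lower (115 and 0 adjusted over the list alone; 25 and 0 after median centring). In the list test it had adjusted p = 1.71e-52, and adjusted p = 0.0756 with an estimated correlation. In OE2 library 1, which stood apart, the median deviation from its siblings lay 0.77 above that of all genes for this list (log2). For genes of short proteins it lay 0.51 above, and for those of long proteins it was -0.61 from that of all genes. Part of the difference between the lines may thus come from that library. Among gibberellin genes 3 of 37 were higher and 0 lower (3 and 0 adjusted over the list alone). The list test gave adjusted p = 0.000437 and was the one that, with all libraries, also passed with an estimated correlation (adjusted p = 0.0241) but not without the pair of libraries that stood apart (adjusted p = 0.309). Carotenoid genes were placed lower in OE2 (adjusted p = 0.000355, and adjusted p = 0.186 with an estimated correlation), with 1 of 40 lower. Without the pair of libraries that stood apart, left out after the data were seen, 6 were lower. The list then passed with an estimated correlation (adjusted p = 0.0094), as it did for OE2 against WT at 18 DAP (adjusted p = 0.0217). In all 459 genes differed at 18 DAP (292 higher in OE2, 167 lower), with 232, 76 and 225 without OE1 library 1, 2 and 3 and 1190 without OE2 library 2. At 10 DAP 560 genes differed (428 higher in OE2, 132 lower; 326 and 247 after median centring), with 232, 288 and 370 without OE1 library 1, 2 and 3 and 204 and 209 without OE2 library 1 and 2. At 10 DAP flavonoid genes were placed higher in OE2 than in OE1: 4 of 13 were higher and 0 lower (5 and 0 adjusted over the list alone). The corresponding list test gave adjusted p = 0.0272, and adjusted p = 0.211 with an estimated correlation. This call ended without the pair of libraries that stood apart (adjusted p = 0.178) and in a fit to the compared libraries alone (adjusted p = 0.18). In the same comparison the cuticle and epidermis markers were placed higher in OE2, with 3 of 20 higher and 0 lower (adjusted p = 0.00949, and adjusted p = 0.971 with an estimated correlation). The phloem markers were placed lower, with 2 of 30 lower and 0 higher (adjusted p = 0.0272, and adjusted p = 0.971 with an estimated correlation). Both marker calls ended without the pair of libraries that stood apart (adjusted p = 0.0729 and 0.0729) and in a fit to the compared libraries alone (adjusted p = 0.24 and 0.0541). The phloem call also ended with median centring (adjusted p = 0.0637) and without OE1 library 2 or OE2 library 2 (adjusted p = 0.125 and 0.188).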

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

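The tests of the younger-fruit, other-tissue and scaling explanations, and of slower development in OE1, were chosen after the results were seen.

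The change from 10 to 18 DAP differed between the OE lines and WT by the test of the difference itself for 1656 genes. Of 100 splits of the genotype labels within the ages, 1 gave as many, the real one, and the highest of the others gave 1582. That split kept the WT libraries of 18 DAP together and labelled every WT library of 10 DAP as OE. A difference at 18 DAP alone can thus give nearly as many calls. The share of splits therefore cannot decide whether the change with age differed, and no conclusion is drawn from it. The named genes with a larger value in OE, as the mean OE change minus the WT change, were proline-rich 33 kDa extensin-related protein-like (Cla97C05G108920) at 6.34, Lipid transfer protein (Cla97C07G143380) at 6.07, Pathogen induced 4 protein (Cla97C06G116580) at 4.83, vacuolar iron transporter homolog 2.1-like (Cla97C09G176620) at 4.74, Pectate lyase (Cla97C03G054380) at 4.50, Expansin (Cla97C06G125700) at 3.98, 9-cis-epoxycarotenoid dioxygenase, putative (Cla97C07G137780) at 3.18, 18 kDa seed maturation protein (Cla97C04G069720) at 4.56, gibberellin 3-beta-dioxygenase 1-like (Cla97C09G164590) at 2.58, Cytokinin riboside 5'-monophosphate phosphoribohydrolase (Cla97C10G203450) at 3.37 and Abscisic stress-ripening protein 1 (Cla97C08G146160) at 3.88. Those with a smaller value were desiccation-related protein PCC13-62-like (Cla97C06G113860) at -6.45, Ribulose bisphosphate carboxylase small chain (Cla97C05G104530) at -4.84, delta(7)-sterol-C5(6)-desaturase-like (Cla97C07G141640) at -4.83, stem-specific protein TSJT1-like (Cla97C01G022730) at -4.57, Oxygen-evolving enhancer protein 1 (Cla97C01G015370) at -3.24, Alkaline alpha-galactosidase seed imbibition protein (Cla97C11G223970) at -3.68 and Bidirectional sugar transporter SWEET (Cla97C06G127900) at -3.74.

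WT library 1 at 10 DAP lay nearer the OE libraries than its siblings. Genes called with age in both OE lines deviated in it towards the younger level in 81.3% of 5503 genes, so a younger fruit is a candidate explanation. On the first principal component OE1 and OE2 of 10 DAP averaged -76.25 and -92.31, further from 18 DAP than WT libraries 2 and 3 (-44.26 and -33.24). OE RNA could thus give a high share too, so the share does not tell these explanations apart. The values were not centred, and the median TPM was 18.74 in library 1 against 16.4 and 15.04 in its siblings. Genes that separated every OE library from the other WT libraries at both ages, with little change in age, numbered 6. WT library 1 was nearer the OE mean in 83.3% of them, which a label error or OE RNA would also give. The exception was a gene of unknown function (Cla97C06G111490), listed at 0 in WT library 1 and its siblings, against an OE mean of 2.88 (log2). A whole OE library under this label would not be at 0 there. The other genes lay from 0.586 to 1.02 of the way from the siblings' mean to the OE mean, most of them short of it. With so few genes both explanations stay open, and no label records the stage of a fruit.

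OE2 library 1 at 18 DAP stood apart from its siblings. Genes for long proteins, picked by description, deviated from the siblings by -1.12 more than genes for short proteins (medians over 417 and 189 genes, log2), so loss of long transcripts, as in degraded RNA, may explain it. Without its 10 most abundant genes its mean r with the siblings was still 0.897, against 0.97 between them. Rescaling shifts the log2 values of the remaining genes nearly alike, so r could hardly move. Whether a few genes took much of the library is thus not decided by that r. The 10 most abundant genes held 13.39% of its TPM, against 9.323% and 9.269% in its siblings. In the WT libraries of 18 DAP they held 14.22% to 15.52%. So a few genes did not take most of OE2 library 1. The seed storage list, the highest of 3 lists of other tissue, lay 0.424 above all genes, with an SD of 1.04 over its members. That spread is too wide to decide on those tissues, and further tissues had no list. The chlorophyll and photosynthesis list lay 1.09 above all genes. Transcript lengths were not used here, and no biological explanation was tested.

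At 18 DAP the OE libraries lay between WT of 10 and 18 DAP on the first principal component. In the 1467 genes higher in both lines, median centring moved the median log2 fold from 1 (quartiles 0.72 and 1.45) to 0.68 (quartiles 0.40 and 1.13) in OE1 and from 1.17 (quartiles 0.82 and 1.77) to 0.98 (quartiles 0.63 and 1.58) in OE2, with a median SE of 0.225 before and 0.225 after. So 68.1% of the fold was left in OE1 and 83.6% in OE2, and 30.9% kept their call under both median centring and quantile normalization, the other calls ending as smaller folds met about the same SE. The genes were picked for high folds, so whether scaling adds to their number stays open. After median centring, 67.1% of the genes called with age in OE1 lay on the younger side of WT in OE2, as slower development would give. The share was 65.2% without the pair of doubted libraries. Of the genes called with age in OE2, 49.4% did so in OE1, so the signs alone showed no such shift for OE1. That share takes no account of the size of a change. On the first principal component, from values not centred by library, OE1 was at 73.7 ± 4.43 and WT at 101 ± 4.19 (SD, n = 3). Slower development in OE1 is thus not decided. In OE2, slower development cannot be told apart from fruit picked at another stage, since no label records ripeness.

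Other splits of the libraries were counted for every comparison. For both lines at 18 DAP 2 of 100 splits gave at least the real 1827 genes, and the highest other gave 1889. That split regrouped OE libraries alone, and the 98 splits that changed the WT group gave at most 3. A random labelling of these libraries can thus be excluded. Chance differences between fruit or plants cannot, since no label says that the libraries of a group came from separate ones. For both lines at 10 DAP 28 of 100 splits gave at least 1 gene and the highest 101, so chance cannot be excluded, and that split put WT library 1 with OE libraries. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of splits with as many calls was 1 for all such comparisons except OE2 against WT at 10 DAP, where it was 3. The real count and the highest other were 7917 and 1 for 18 against 10 DAP in WT, 7756 and 1 for the same ages in OE1, 8012 and 3 for those in OE2, 645 and 186 for OE1 against WT at 10 DAP, 4 and 262 for OE2 against WT at 10 DAP, 560 and 2 for OE2 against OE1 at 10 DAP, 2254 and 2 for OE1 against WT at 18 DAP, 4350 and 2 for OE2 against WT at 18 DAP and 459 and 1 for OE2 against OE1 at 18 DAP. For OE1 and for OE2 against WT at 10 DAP the split with the highest count put WT library 1 with libraries 1 and 2 of the line. For OE2 and for both lines at 10 DAP such a split gave far more calls than the real one (262 against 4, and 101 against 1), a structure of the samples.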

How the results depend on the processing

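Leaving out both libraries that stood apart was chosen after the data were seen. Each lay far from its siblings, so leaving it out narrows the spread. WT library 1 of 10 DAP also lay near OE, so calls against WT at that age tend to rise by that choice. No named gene or list call turned its direction under any alternative run. Depth is unknown, and low genes rest on the pseudocount. The number of genes called was 1035 for OE1 against WT at 10 DAP, 2 for OE2 against WT at 10 DAP, 1308 for OE1 against WT at 18 DAP, 0 for both lines at 10 DAP and 1111 for both lines at 18 DAP with quantile normalization; 2 for OE2 against WT at 10 DAP and 0 for both lines at 10 DAP with median centring; 369 for OE2 against WT at 10 DAP and 52 for both lines at 10 DAP with no filter; 1 for OE2 against WT at 10 DAP, 354 for OE2 against OE1 at 10 DAP and 0 for both lines at 10 DAP with the stricter filter, where fewer genes were tested; 397 for OE1 against WT at 10 DAP, 7 for OE2 against WT at 10 DAP and 2 for both lines at 10 DAP with a pseudocount of 0.1; 946 for OE2 against WT at 10 DAP and 155 for both lines at 10 DAP with a pseudocount of 5; 368 for OE2 against WT at 10 DAP and 52 for both lines at 10 DAP without the variance trend. An added minimum log2 fold of 1 gave 4838 for 18 against 10 DAP in WT, 4596 for 18 against 10 DAP in OE1, 4720 for 18 against 10 DAP in OE2, 1114 for OE1 against WT at 18 DAP, 2227 for OE2 against WT at 18 DAP, 272 for OE2 against OE1 at 18 DAP, 0 for both lines at 10 DAP and 892 for both lines at 18 DAP, and removed Cla97C04G070460 with age in WT, Cla97C10G188990 in both lines at 10 DAP and Cla97C09G172410 and Cla97C05G090480 in both lines at 18 DAP, by construction. The compared libraries alone, a fit on fewer samples, gave 4583 for 18 against 10 DAP in OE2, 37 for OE1 against WT at 10 DAP, 1 for OE2 against WT at 10 DAP, 1819 for OE2 against OE1 at 10 DAP, 6291 for OE1 against WT at 18 DAP, 1657 for OE2 against WT at 18 DAP, 2 for OE2 against OE1 at 18 DAP, 0 for both lines at 10 DAP and 896 for both lines at 18 DAP. Without both libraries that stood apart the counts were 5886 for OE1 against WT at 10 DAP, 7453 for OE2 against WT at 10 DAP, 2676 for OE2 against OE1 at 10 DAP, 6717 for OE1 against WT at 18 DAP, 8470 for OE2 against WT at 18 DAP, 1120 for OE2 against OE1 at 18 DAP, 4967 for the difference in change, 4282 for both lines at 10 DAP and 5651 for both lines at 18 DAP. Except where an alternative's construction is named, the cause was not tested. The other counts stayed within 1.5 times of the reported values.

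With the replicate number as a block the count was 299 for OE2 against WT at 10 DAP and 49 for both lines at 10 DAP, and the list tests passed 77 times, with none of the reported calls lost. The block ended the calls of Cla97C05G090480 in both lines at 18 DAP (adjusted p = 0.052) and of Cla97C10G188990 in both lines at 10 DAP (adjusted p = 0.0627), and no other call of a named gene. Libraries that shared a number had deviations correlated at a mean of 0.00827 and others at -0.00477, and 8 of 18 libraries correlated best with their own number, so the libraries share only a number. The list tests passed 76 times over 10 comparisons and 1 time with an estimated correlation.

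With each library of the compared groups left out in turn, the counts ran from 6768 to 7709 for 18 against 10 DAP in WT, from 6591 to 6889 for 18 against 10 DAP in OE1, from 6517 to 8789 for 18 against 10 DAP in OE2, from 72 to 2651 for OE1 against WT at 10 DAP, from 2 to 3446 for OE2 against WT at 10 DAP, from 0 to 1754 for both lines at 10 DAP, from 204 to 814 for OE2 against OE1 at 10 DAP, from 1246 to 1403 for OE1 against WT at 18 DAP, from 3168 to 7500 for OE2 against WT at 18 DAP, from 1051 to 4653 for both lines at 18 DAP, from 76 to 1190 for OE2 against OE1 at 18 DAP, from 935 to 3809 for the difference in change and from 71 to 85 for the list tests. The lowest and highest counts came without WT library 2 and WT library 1 for the OE lines at 10 DAP, and without WT library 2 and OE2 library 1 for both lines at 18 DAP.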

Other observations

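The genes described here were chosen after their values were seen. At 10 DAP a sulfate transporter gene (Cla97C07G136270) was 42.3 ± 6.09 TPM in OE1, 6.82 ± 4.13 TPM in OE2 and 3.01 ± 5.14 TPM in WT, and a response to low sulfur protein gene (Cla97C01G000020) 308 ± 49.8 TPM, 134 ± 14.5 TPM and 49.5 ± 78.1 TPM. A gamma-glutamylcyclotransferase gene (Cla97C08G155750), of glutathione breakdown, was 103 ± 7.56 TPM in OE1, 31.5 ± 9.25 TPM in OE2 and 26.12, 0 and 0 TPM in the WT libraries. They passed in OE1 at 10 DAP (limma adjusted p = 0.0267, 0.0224 and 0.0166) and not in OE2 (adjusted p = 0.32, 0.0755 and 0.0775). OE2 against OE1 gave adjusted p = 0.176, 0.61 and 0.458. In OE1 against WT each call ended without WT library 2 or 3 or OE1 library 1 or 2, and for the first pair also without OE1 library 3 (adjusted p up to 0.162, 0.143 and 0.111). Each also ended in a fit to the compared libraries alone (adjusted p = 0.103, 0.154 and 0.128). WT library 1 held 139.58 TPM of the low-sulfur gene, above its siblings at 4.59 and 4.18 TPM.

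Each OE library lay above each WT library at both ages for 199 of 17150 genes (1.16%) and below for 47 (0.274%), where chance gives 0.0142% in each direction. That share holds for exchangeable libraries, and the values were not centred. The median TPM averaged 18.13 in OE1, 19.5 in OE2 and 16.73 in WT at 10 DAP. At 18 DAP it averaged 16.71, 15.61 and 13.18, so scaling may add to the genes above WT. Among the genes above WT at both ages, 1 annotated only as protein kinase 1 (Cla97C02G038540) had 17.5 ± 2.57 TPM in WT, 166 ± 24.3 TPM in OE1 and 225 ± 46.2 TPM in OE2 at 18 DAP. At 10 DAP its WT libraries were at 497.38, 43.84 and 45.45 TPM, with library 1 the highest, against 974 ± 65.2 TPM in OE1 and 991 ± 410.4 TPM in OE2. The description does not place it in a kinase family, and it is not taken for the overexpressed gene.

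The most abundant gene at 18 DAP in WT was an unknown protein (Cla97C10G193250), at 62070 ± 8395 TPM in WT, 13207 ± 4543 TPM in OE1 and 12544 ± 2810 TPM in OE2 (limma adjusted p = 0.0354 and 0.0181), a call lost with quantile normalization (adjusted p = 0.192) and without WT libraries 1, 2 or 3 of 18 DAP or OE1 libraries 1, 2 or 3 of 18 DAP or OE2 library 3 of 18 DAP (adjusted p up to 0.114). Abscisic stress-ripening protein 1 (Cla97C08G146160) was 22730 ± 639 TPM, 33178 ± 5938 TPM and 30289 ± 7753 TPM at 18 DAP and 2250 ± 1647 TPM, 188 ± 17.6 TPM and 148 ± 147 TPM at 10 DAP. At 10 DAP its WT libraries were at 348.16, 3225.37 and 3177.09 TPM.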
